A study of Drosophila melanogaster with 3 samples.

How the data were processed

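The series profiled the origin recognition complex (ORC) in Kc167, a female Drosophila melanogaster cell line derived from embryos. ORC is the protein complex that marks sites where DNA replication can start, and it was recovered by chromatin immunoprecipitation with a rabbit polyclonal antibody against its ORC2 subunit, followed by sequencing (ChIP-seq). Per the labels' protocols, asynchronous cultures were crosslinked, chromatin was extracted and immunoprecipitated, and Illumina libraries were made. The labels describe 3 samples, which are 2 ORC2 ChIP libraries from separate extractions and 1 input DNA sample. The input was not analysed here as a sample of its own, because the values used come from peak lists of the ChIP libraries.

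The authors deposited peak lists, 1 for each ChIP replicate and 1 for the series. Per the file headers the coordinates are on FlyBase release 5, and the source column of each file names PeakSeq, a peak caller. The aligner, the read depth, the PeakSeq version and the calling threshold are not given in the sources used here. The deposited score of a peak is the authors' own value, never negative, and its unit is not stated. It was used to describe, rank and filter peaks within a list. Among replicate 1 peaks, 44.1% had exactly the same score as at least 1 other peak of that list, and 98.8% of the 5997 pairs of equal scores lay on the same chromosome, against a mean of 18.0% when scores were permuted over peaks. In replicate 2, 98.8% of 3676 such pairs lay on the same chromosome. Whether scores on different chromosomes share a common scale is therefore open. Several comparisons pool scores over chromosomes. The score difference between shared and unshared peaks, and the overlap and spacing of the higher-scoring 50%, were repeated with scores ranked within each chromosome, an alternative added after the data were seen. No read counts are in these lists, so the depth behind each peak is unknown, and intervals on shares and densities cover counting error of peaks only.

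The list of the whole series was compared with the replicates before use. Each of its 5159 peaks had as its limits the outer limits of overlapping peaks from both replicates. The score was the mean of the joined peaks' scores in 5133 of them, within a tolerance of 0.0001, including the 4995 that join 1 peak of each replicate. It is referred to as the joined list, and it is not an independent measurement.

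Coordinates were read as the files give them (counted from 1, both ends included). A peak was called shared when at least 1 bp of it was covered by a peak of the other replicate. Reproducible peaks are the replicate 1 peaks that are shared. Random expectation came from 1000 shuffles that kept each peak's width and chromosome arm and drew its position uniformly. Two-sided permutation p-values from 1000 shuffles cannot go below 0.002, and those from 100 shuffles, used for the rules that ask for 50% overlap, cannot go below 0.0198. Chromosome lengths were taken as the largest peak end on each chromosome in either replicate, because no release 5 genome was used here. Sequence gaps could not be left out of the shuffles. Widths and scores of shared and unshared peaks were compared by the difference of medians with 100000 permutations of the shared label over peaks, for which the smallest p is 1e-05. The X chromosome was compared with the autosomes by shuffling peaks over 2L, 2R, 3L, 3R, 4 and X, and again by permuting blocks of 1 Mb between X and autosomes, with 95% intervals from 10000 resamples of the blocks. Clustering was measured by the median distance from a peak's midpoint to that of its nearest neighbour. The variance to mean ratio of peak counts in windows of 100 kb was the other measure. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals, and those on densities are exact 95% Poisson intervals. Peaks are not independent replicates, and with 2 ChIP samples no test across samples was possible, so the main comparisons are given for both replicates. Some further values are given for replicate 1 only.

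Apart from the widest peak of replicate 2, which was singled out after its width was seen, the peaks named in the report were chosen by a rule set before the data were examined. The rule takes the 10 highest scores of the joined list, the 5 windows of 100 kb with the most reproducible peaks, and the 5 highest-scoring peaks of each replicate that the other lacks. The gene-based parts of the plan (start sites, 22 gene lists, annotation classes and base composition) were not run, because the gene table at hand is on release 6 and positions were not converted between releases. Alternatives set in advance were other overlap rules, a stricter score threshold, each replicate alone, the joined list, other window sizes and shortened arms.

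Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The computations were checked on simulated lists whose answers were set in advance. In a list of 6593 peaks, 40% were exact copies of peaks in another list, and 39.9% came back after subtracting random overlaps. With 5000 peaks placed at an X to autosome ratio of 1.3, the ratio came out at 1.30. Both values follow from how the lists were built, and these peaks were placed without clustering. They show that the measures are computed correctly, not how the tests perform on real peaks. The median test on 2000 simulated values with a planted difference of 0.5 gave 0.506.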

Results

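ORC2 binding was mapped in asynchronous Kc167 cells in 2 ChIP-seq replicates from separate extractions. The authors' peak lists held 8970 peaks in replicate 1 and 6593 peaks in replicate 2. Replicate 1 peaks covered 1.61 Mb with a median width of 124 bp (interquartile range 68.0 to 231 bp). Replicate 2 peaks covered 1.00 Mb with a median width of 104 bp (interquartile range 59.0 to 176 bp). Of the replicate 2 total, 6.33% came from a single peak of 63.5 kb on 2RHet (3212924 to 3276381), and the next widest peak of that replicate was 1833 bp. The median score was 2.66 in replicate 1 and 2.72 in replicate 2. Peaks under 10 bp made up 4.99% of replicate 1 and 5.22% of replicate 2. Read depth is unknown for both libraries, so the difference in the number of peaks cannot be set against it. All positions are on FlyBase release 5, and the genes around them were not analysed here.

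The first comparison asked which ORC2 sites were found in both replicates. In replicate 1, 5185 of 8970 peaks (57.8%, 95% interval 56.8 to 58.8%) were overlapped by a replicate 2 peak. In replicate 2, 5309 of 6593 peaks (80.5%, 79.5 to 81.5%) were overlapped by a replicate 1 peak. Shuffled positions gave 1.66% and 2.24% on average, so the observed shares were 34.9 and 35.9 times the random expectation (two-sided permutation p = 0.002 for each, the smallest that 1000 shuffles can give). Requiring 50% reciprocal overlap lowered the shares to 39.3% and 53.5%. The bases covered in both replicates made up 43.7% of the bases covered in either, and 45.3% without the 63.5 kb peak on 2RHet, inside which replicate 1 had 1 peak of 60 bp. The joined list of 5159 peaks held the shared sites only. Every peak in it overlapped both replicates, and no shared peak of either replicate lay outside it.

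Shared sites were wider and higher in score than sites found once. In replicate 1 the median width was 177 bp for shared and 70 bp for unshared peaks, a difference of 107 bp. In replicate 2 the medians were 123 and 39.0 bp, a difference of 84.0 bp. The median score was 2.93 for shared and 2.24 for unshared peaks in replicate 1, and 2.81 against 2.30 in replicate 2. Each of these 4 differences had a two-sided permutation p of 1e-05, the smallest possible, and a Benjamini-Hochberg adjustment over the 4 leaves it unchanged. The ratio of shared to unshared medians was 2.53 for width and 1.31 for score in replicate 1, and 3.15 and 1.22 in replicate 2. Of the narrowest 10% of replicate 1 peaks, 9.70% (7.84 to 11.8%) were shared, against 91.1% (89.0 to 92.9%) of the widest 10%. The corresponding shares were 35.2% and 98.3% in replicate 2. Width itself helps a peak to meet the 1 bp rule, so the rule can add to these width differences and shares. By score, 23.5% of the lowest 10% of replicate 1 peaks and 74.1% of the highest 10% were shared, and in replicate 2 these shares were 63.1% and 83.6%. In both replicates the share was higher in the next lower 10% by score, at 76.5% and 89.1%. With scores expressed as percentiles within their chromosome, the medians of shared and unshared peaks were 61.5 and 31.4 in replicate 1 and 53.3 and 34.2 in replicate 2 (permutation p = 1e-05 for each). Of the 514 replicate 1 peaks in the top 25% of both measures, 15 (2.92%, 1.64 to 4.77%) lacked a counterpart, as did 1 of 349 in replicate 2.

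**Figure D1:**
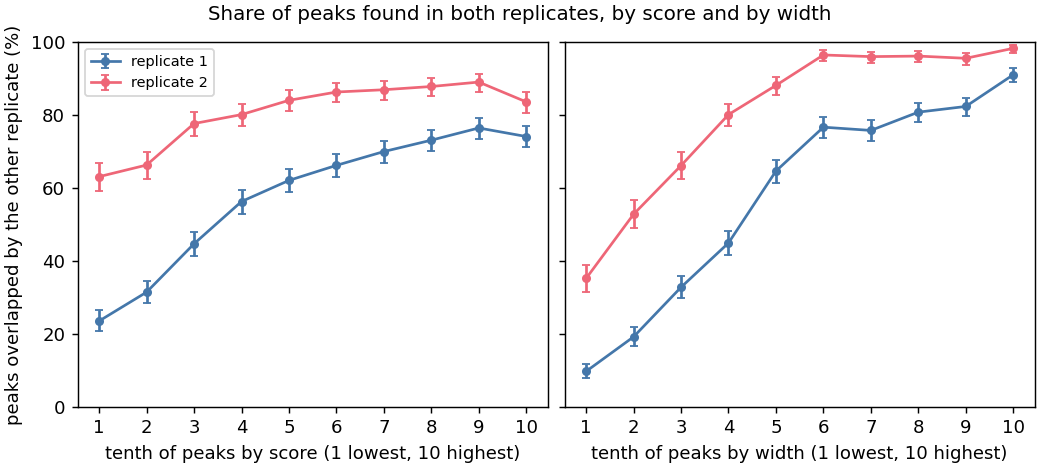
Percentage of peaks overlapped by the other replicate (y axis) for each 10% of peaks ordered by score (left) or by width (right), in replicate 1 and replicate 2; bars are exact 95% binomial intervals. In replicate 1 the share went from 9.70% in the narrowest to 91.1% in the widest 10%, and by score from 23.5% to 74.1%.

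Unshared peaks lay closer to peaks of the other replicate than shuffled positions did. The shuffles did not keep the short-range clustering of peaks described below, and no comparison that keeps it was run. The difference is therefore not shown to be particular to unshared peaks. Of 3785 unshared replicate 1 peaks, 1400 (37.0%, 35.4 to 38.5%) were within 1 kb of a replicate 2 peak, against a mean of 8.36% and a maximum of 9.73% in shuffles within blocks of 1 Mb (permutation p = 0.002). Of 1284 unshared replicate 2 peaks, 585 (45.6%, 42.8 to 48.3%) were within 1 kb of a replicate 1 peak, against 10.5% in shuffles (permutation p = 0.002). This distance was chosen after the data were seen.

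Where 1 peak of each replicate overlapped, 4995 pairs were formed and their values compared. Midpoints differed by a median of 17.0 bp, and in 90% of pairs they lay within 90 bp of each other. Paired peaks had to overlap, so the pairing rule itself limits how far their midpoints can differ. The replicate 2 peak was narrower in 79.4% of pairs, with a median width ratio of 0.785. Scores were correlated across pairs, with Spearman's rho of 0.769 and Pearson's r of 0.792 on log2 scores (permutation p = 1e-05 for each, the smallest possible). These are correlations across peaks, which are not independent replicates. The labels list 1 input sample, and whether it served as the control for both peak lists is not given in the sources used here. A shared control could raise the overlap of the lists and this correlation without common ORC2 signal. With log2 scores centred on each chromosome's median, rho was 0.780 and r was 0.805. The median ratio of the replicate 2 to the replicate 1 score lay between 0.945 on 2L and 1.02 on 3R for the large arms. On U, which collects sequence not assigned to a chromosome, it was 0.490 over 30 pairs.

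**Figure D2:**
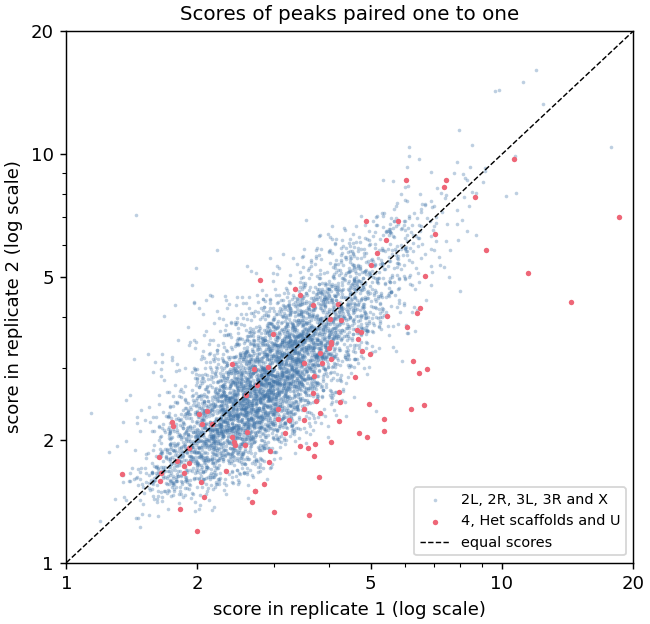
Score of each of 4995 pairs of overlapping peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log scales without a stated unit; the dashed line marks equal scores. Points on 2L, 2R, 3L, 3R and X spread around the line, whereas 75.9% of the 108 pairs on 4, the Het scaffolds and U had a lower score in replicate 2.

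The highest-scoring sites were spread over 7 chromosomes or scaffolds. In the joined list the highest score was 14.1 on X at 12861518 to 12861607, where replicate 1 gave 17.8 over 11 bp and replicate 2 gave 10.4 over 90 bp. A score of 14.0 followed on 3R at 12323226 to 12323302 (11.95 in replicate 1 and 16.0 in replicate 2). The other 3R site, at 15316847 to 15316990, had 13.1. On 2R, the site at 711780 to 711898 had 12.9, with replicate scores of 12.4 and 13.3, and the site at 3295317 to 3295458 had 12.1. The site on U at 2184288 to 2184451 had 12.8, but its replicate scores of 18.5 and 7.004 differed most among these 10. On 2L, sites at 11948580 to 11948737 and 19393823 to 19393991 had 11.96 and 9.70. The site on 3L at 9435326 to 9435447 had 10.3 and that on chromosome 4 at 230696 to 230912 had 10.2, with replicate scores within 1 unit of each other at both. Whether scores share a scale across chromosomes is not given in the sources used here, so the order of sites on different chromosomes stays open.

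Some peaks with high scores were absent from the other replicate, and these were short. Replicate 1 had scores of 41.8 and 20.9 on U (5599361 to 5599386 and 2151670 to 2151740), 13.7 on 2L (9567535 to 9567565), 12.2 on U (514203 to 514236) and 11.4 on 2R (3502992 to 3503091). Replicate 2 had scores of 15.7 on U (5288287 to 5288296), 14.6 on 2RHet (1623512 to 1623573), 13.8 on 3LHet (459525 to 459547), 13.02 on chromosome 4 (201787 to 201843) and 12.5 on U (6446295 to 6446318). All of these 10 peaks were 10 to 100 bp wide. Most lay on U, the Het scaffolds or chromosome 4, where fewer peaks were shared than on the large arms. On U the median ratio of the replicate 2 to the replicate 1 score was 0.490 over 30 pairs. Whether scores there can be set against those on other chromosomes is open, so these peaks cannot be read as strong sites missed by 1 replicate. The peaks on 2L and 2R can be ranked within their own arm. The 2L score of 13.7 was above the replicate 1 score of 9.63 at the highest-scoring 2L site of the joined list. The 2R score of 11.4 lay between the replicate 1 scores of 12.4 and 9.83 at the 2R sites named above. With read depth unknown, whether replicate 2 missed true sites at these positions is open.

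The distribution over chromosomes was compared next. Kc167 cells are female. ORC2 sites were densest on X. Reproducible peaks reached 51.0 per Mb on X (95% interval 48.1 to 54.0), 45.5 (42.6 to 48.4) on 2R, 41.8 (39.4 to 44.2) on 3R, 38.5 (36.1 to 41.1) on 3L and 37.5 (34.99 to 40.04) on 2L. X was also the densest of the large arms in each replicate alone, with 80.0 peaks per Mb against 69.2 on the autosomes in replicate 1, and 61.8 against 51.3 in replicate 2. The X to autosome ratio of reproducible peaks was 1.26, against a 95% range of 0.930 to 1.06 in shuffles (permutation p = 0.002). Resampling blocks of 1 Mb gave a 95% interval of 1.12 to 1.39, and a two-sided permutation test of the blocks gave p = 0.00203. X blocks held 51.8 ± 10.2 peaks (SD over 22 full blocks) and autosomal blocks 41.2 ± 12.8 (SD over 95 full blocks). Against single arms, permutation of the blocks with Benjamini-Hochberg adjustment over 4 arms gave an adjusted p of 0.00228 for 2L, 0.0027 for 3L and 0.0166 for 3R, while the difference from 2R was within the spread between blocks (adjusted p = 0.107). When peaks less than 5 kb apart were counted as 1, the ratio was 1.10 and its block interval, 0.992 to 1.22, included 1.

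**Figure D3:**
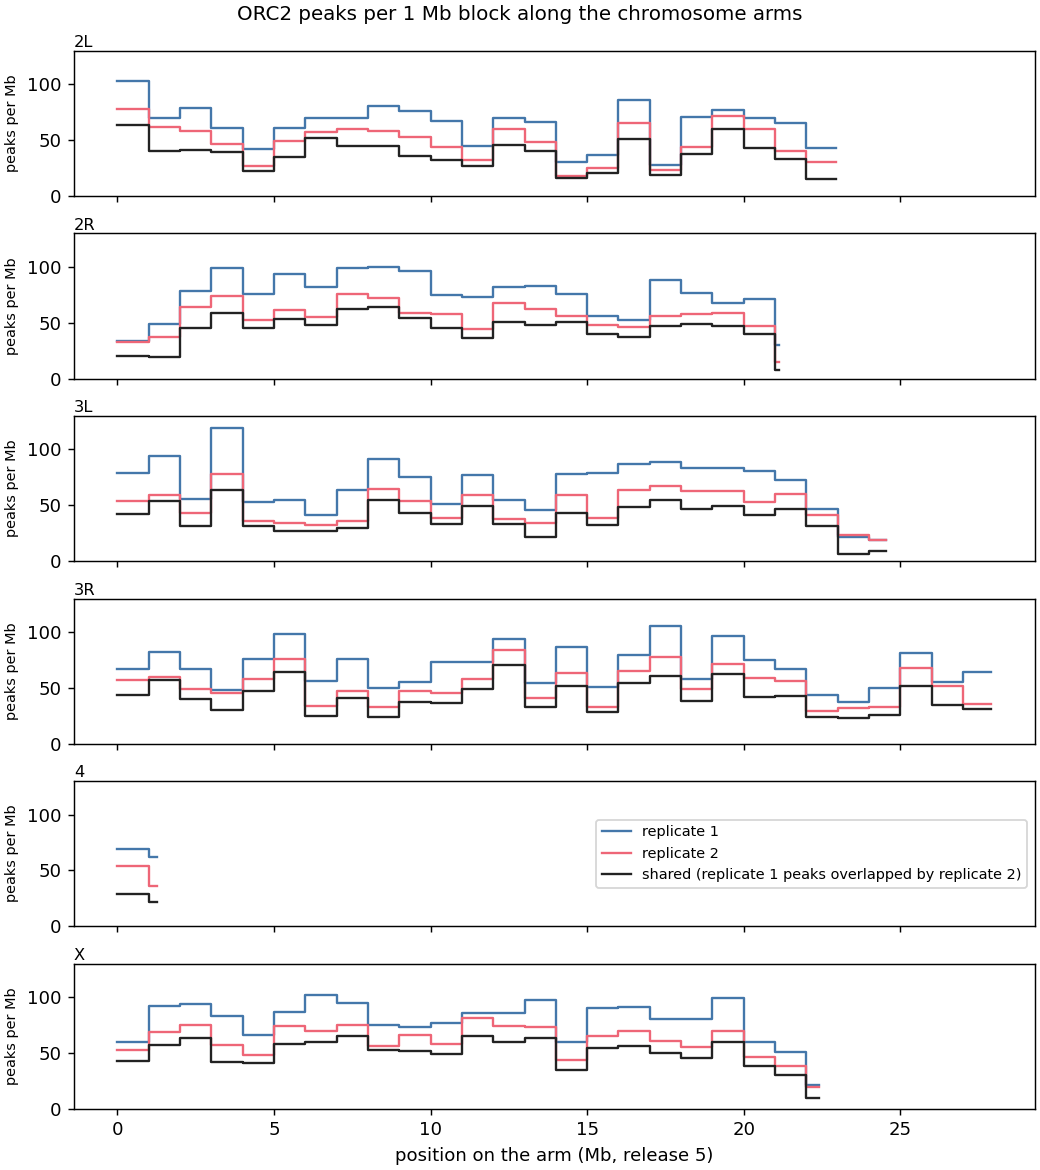
Peaks per Mb (y axis) in consecutive blocks of 1 Mb along each arm (x axis, Mb on release 5) for replicate 1, replicate 2 and the shared peaks. Shared peaks averaged 51.0 per Mb on X and between 37.5 and 45.5 on the large autosomal arms, and the curves drop towards the ends of 2L, 3L and X and the start of 2R.

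Chromosome 4 and the heterochromatic scaffolds held fewer shared sites. Chromosome 4, a small and largely heterochromatic chromosome, had 27.4 reproducible peaks per Mb (19.1 to 38.1), but 67.4 peaks per Mb in replicate 1 alone and 50.1 in replicate 2 alone, close to the 71.2 and 53.3 of the 5 large arms. The 5 Het scaffolds, which carry mapped heterochromatin in release 5, had 5.34 reproducible peaks per Mb together, against 17.9 and 15.1 in the single replicates. XHet, taken as 0.0849 Mb long, was an exception at 35.3 per Mb, but this rests on 3 shared peaks of 4 in replicate 1. Its length is the largest end among a few peaks, so it may be too short and the density too high. U had 3.36 per Mb (2.27 to 4.79), against 29.1 in replicate 1 and 6.72 in replicate 2. In replicate 1, 40.7% (30.2 to 51.8%) of peaks on chromosome 4, 29.9% (22.8 to 37.8%) on the Het scaffolds and 11.5% (7.92 to 16.1%) on U were shared, against 59.9% (58.9 to 61.0%) on the 5 large arms. In replicate 2 these shares were 56.2% (43.3 to 68.6%), 36.9% (28.6 to 45.8%) and 30 of 60 (36.8 to 63.2%), against 82.0% (81.0 to 82.9%). None of these intervals overlapped that of the large arms. U carried 260 peaks in replicate 1 and 60 in replicate 2, which is 2.90% and 0.910% of each list. How much of the Het and U sequence could be mapped by short reads is not given in the sources used here.

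The spacing of sites was compared with random placement, and ORC2 peaks as called were clustered. Each called peak counted as a separate site, and the measures below were not repeated after joining close peaks. A broad region called as several peaks would therefore also count as clustering. The median distance from a reproducible peak to its nearest neighbour was 3131 bp, against 8249 bp on average in shuffles within each arm (permutation p = 0.002). Peak counts in windows of 100 kb over all chromosomes and scaffolds had a variance to mean ratio of 3.64, against 1.498 in shuffles (permutation p = 0.002). Differences in density between chromosomes add to both values. On 2L, 2R, 3L, 3R, 4 and X only, added after seeing the data, the ratio was 3.22, against 1.06 in shuffles (permutation p = 0.002). Over 2L, 2R, 3L, 3R, 4 and X, 107 of 1205 windows held 10 or more reproducible peaks and 167 held none. In 200 shuffles, the largest such counts were 27 and 31. Each replicate alone was clustered too, with median distances of 1354 bp in replicate 1 and 2300 bp in replicate 2, against 5044 and 6670 bp in shuffles. For the higher-scoring 50% of reproducible peaks the distance was 8911 bp, against 16571 bp in shuffles, and the variance to mean ratio was 1.99, against 1.24.

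The densest windows held runs of closely spaced peaks. On 3R, 27 reproducible peaks lay between 12006324 and 12086876, and 26 between 17405288 and 17497518. These windows had 6.46 and 6.23 times the mean density of that arm, and the highest count in any window of 200 shuffles was 16. On 2L, 20 peaks lay between 19114298 and 19186088. On 3L, 20 lay between 8627169 and 8698560, and on X, 20 lay between 12505867 and 12579261. Replicate 1 alone had 33, 41, 27, 29 and 25 peaks in these windows, in the order given, and replicate 2 alone had 32, 37, 25, 22 and 26. The windows were chosen by peaks found in both replicates, so high counts in each follow from that choice. Their median widths were 451, 340, 201, 330 and 346 bp, against 177 bp over all reproducible peaks, while their median scores of 2.61, 2.54, 2.17, 2.70 and 2.61 were each below the median of reproducible peaks on their own arm (2.84 on 3R, 2.86 on 2L, 3.08 on 3L and 2.89 on X). Without the 3R windows the variance to mean ratio was 3.47.

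**Figure D4:**
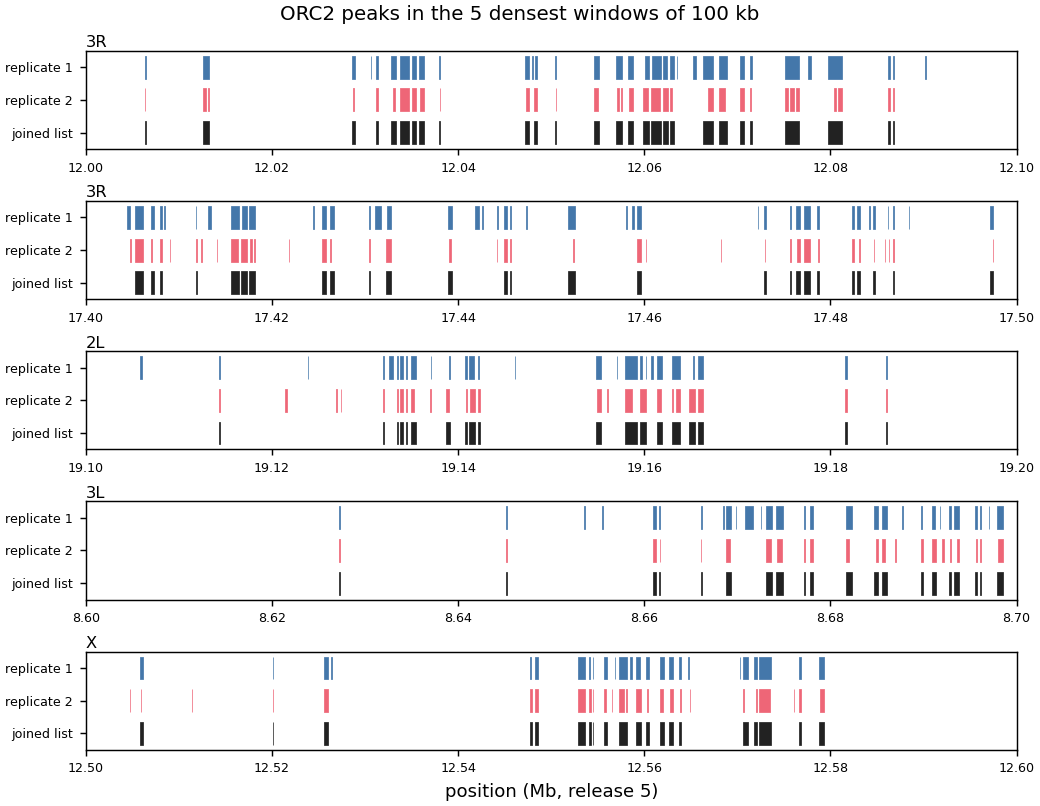
Positions of peaks (x axis, Mb on release 5) in replicate 1, replicate 2 and the joined list in the 5 windows of 100 kb with the most reproducible peaks; each bar spans a peak. Most bars of the joined list fall into runs, such as the 27 peaks on 3R between 12006324 and 12086876.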

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

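The overlap between replicates, the width and score differences, the X to autosome ratio and the clustering measures kept their direction and passed their shuffle or permutation tests under the alternatives run. For the X to autosome ratio, the intervals from resampled blocks included 1 in 2 cases. These were peaks less than 5 kb apart counted as 1 (1.10, 0.992 to 1.22, with a permutation p of 0.046 from the shuffle) and the highest-scoring 25% (1.13, 0.957 to 1.31, with no shuffle run). Without replicate 1 or replicate 2, the X to autosome ratio was 1.21 or 1.16, the nearest-neighbour distance 2300 or 1354 bp, and the variance to mean ratio 4.28 or 4.91. Over the alternative overlap rules and filters, the share of replicate 1 peaks with a counterpart ranged from 39.3% (50% reciprocal overlap) to 64.7% (midpoints within 500 bp), and that of replicate 2 from 53.5% (50% reciprocal overlap) to 87.5% (peaks of at least 50 bp, added after seeing the data). With sharing judged by midpoints within 500 bp instead, a rule that width does not help to meet, added after seeing the data, the median widths of shared and unshared peaks were 164 and 71 bp in replicate 1 and 117 and 42 bp in replicate 2 (permutation p = 1e-05 for each). The share of the joined list covered by both replicates moved from 100% to 71.7% when at least 50% of a joined peak's own length had to be covered, because joined peaks take outer limits. The share of unshared replicate 1 peaks near a replicate 2 peak was 23.1% within 500 bp and 49.1% within 2 kb. Taking the higher-scoring 50% of both lists gave overlaps of 54.8% and 75.2%. With the cut made within each chromosome, added after seeing the data, these were 55.1% and 75.5%. Both lists were cut, so a peak also counted as unshared when its counterpart fell below the other list's cut. Against the full other list, each 10% of peaks above the median score had 66.2 to 76.5% shared in replicate 1. In replicate 2 this was 83.6 to 89.1%. The cut within each chromosome gave a variance to mean ratio of 1.999, against 1.25 in shuffles. Restricting to the higher-scoring 50% left 9, 9, 3, 8 and 7 peaks in the 5 dense windows. Leaving out 1 Mb or, added after seeing the data, 3 Mb at each arm end, which also removes chromosome 4, gave X to autosome ratios of 1.28 and 1.27. Of the density values for single chromosomes and scaffolds, 32 moved by more than 1 SD of the 2 replicates and 28 did not, and this SD is wide where the replicates differ, as on U. Of the counts in the dense windows, 6 moved by more than 1.5 times and 19 did not. The 10 named peaks could not move by more than their SD, because the joined score is the mean of both replicates. No read depth stands behind any value, so weak sites missing from a replicate cannot be told from undetected ones. The alternatives on start sites, gene lists, base composition and annotation classes were not run. No paired analysis was possible because the input has no peak list here and shares only replicate number 1 with the ChIP samples.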

Other observations

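Long stretches of the arms carried few or no shared ORC2 sites. These intervals were chosen after their values were seen. Between consecutive reproducible peaks on 2L, 2R, 3L, 3R, 4 and X, the longest interval was 488 kb on 2L (22473029 to 22960946), followed by 448 kb on 3L (23573984 to 24021493), both near the centromeric end of their arm. They were not empty of peaks, since the 2L interval held 9 replicate 1 and 7 replicate 2 peaks and the 3L interval 6 and 5, none of which were shared. Away from arm ends, 372 kb on 2L (16889064 to 17260645) held 1 replicate 1 peak and 2 replicate 2 peaks. An interval of 313 kb on 3L (9961611 to 10275074) was the only one of the 10 longest without a peak in either replicate. In 200 shuffles the longest interval averaged 221 kb and reached 376 kb at most, so the first 2 exceeded every shuffle. Sequence gaps near the centromeres are not known here.

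Some of the tests below were chosen after the result was seen. These were the tests on U, without U and without nearby pairs, and that on width alone for chromosome 4, the Het scaffolds and U. Equal scores recurred within chromosomes. In replicate 1, 67.5% of the narrowest 25% of peaks and 22.2% of the widest 25% shared their exact score with another peak, and in replicate 2 these were 59.0% and 20.2%. Of the pairs of equal scores, 98.8% lay on the same chromosome, above the maximum of 19.9% over 1000 permutations. This is consistent with a score scale set separately for each chromosome, as a hypothesis, since no source used here describes the scale. Equal scores of peaks near each other are argued against as the whole cause, because without pairs less than 1 Mb apart the share was 98.6%, against a maximum of 18.3% over permutations (98.7% against 19.5% in replicate 2). Other causes of equal scores were not tested. Rankings of sites across chromosomes by this score, and the score ratio of 0.490 between replicates on U, would then depend on those scales.

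X carried 1.26 times the autosomal density of reproducible peaks. A greater readiness to call narrow peaks on X is argued against as the whole cause, because the ratio among the widest 25% of peaks was 1.38 (block interval 1.17 to 1.63). Dense clusters counted peak by peak may contribute. After joining peaks less than 5 kb apart the ratio was 1.10, and its interval of 0.992 to 1.22 leaves this open. Weak peaks called more readily on X may also contribute. The ratio fell from 1.26 among all reproducible peaks to 1.20 (1.07 to 1.34) among the higher-scoring 50%. Among the highest-scoring 25%, the test set in advance, it was 1.13 (0.957 to 1.31). That interval includes 1, so the test does not decide. This explanation stays open, also because scores may not be comparable between chromosomes. No biological explanation was tested, since the study has no samples that differ in X.

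Peaks on chromosome 4, the Het scaffolds and U were shared less often than those on the large arms. Narrower peaks there are argued against as the whole cause. In replicate 1, 22.2% (18.6 to 26.1%) of 500 such peaks were shared, where peaks of the large arms in the same 5 classes of width gave 53.2%. In replicate 2 the values were 44.9% (38.7 to 51.2%) against 79.7%. Weaker peaks there stay open. The median score there was higher than on the large arms in replicate 1 (3.06 against 2.63) and lower in replicate 2 (2.36 against 2.73). Large arms matched on score as well gave 56.7% and 78.3%, but the bound set for this test took scores to be comparable between chromosomes, and the equal scores above leave that in doubt. A different score scale on U in the 2 replicates is argued against as the whole cause, since without U 33.8% (27.8 to 40.1%) of 240 replicate 1 peaks were shared, against 53.7% on the large arms at the same width, and 43.3% (36.2 to 50.6%) of 194 replicate 2 peaks, against 78.0%. On U itself, a scale that let fewer replicate 2 peaks pass is argued against as the whole cause, since 30 of the 60 that did pass (50%, 36.8 to 63.2%) were shared, against 85.0% at the same width, but it may contribute to the low share of 11.5% in replicate 1. Repeated sequence, which is common in heterochromatin, may also contribute, and it was not tested because no release 5 sequence was used here.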
